A study of Oryza sativa with 4 samples.

How the data were processed

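DNA methylation was measured by bisulfite sequencing in sperm cells and in vegetative cell nuclei of rice pollen (Oryza sativa, cultivar Nipponbare, carrying a ubiquitin-promoter histone H2B-GFP transgene). Plants were wild type (WT) or heterozygous for a mutation in ROS1a, a DNA glycosylase related to DEMETER that excises methylated cytosine. The vegetative cell is the companion cell of the pollen grain that carries the sperm. Per the labels, nuclei and cells were picked under a microscope from burst pollen and the libraries followed a protocol made for very small inputs. Each of the 4 combinations of cell type and genotype had 1 library, so no difference below has a replicate check, and a test on the calls of a pair of libraries compares those libraries, not the conditions. Pollen of a heterozygous plant is a mixture of grains with the WT and grains with the mutant allele, and their shares in the libraries are not given in the sources used here.

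The submitters' processing notes name Trim Galore and Bismark. Settings, versions, the treatment of PCR copies and the genome build are not given in the sources used here. The deposited files gave, for each library and each of the 3 cytosine contexts (CG, CHG and CHH, where H is A, C or T), 50-bp windows with a methylation level as a fraction from 0 to 1, with the methylated and unmethylated calls behind it. The level was checked to be methylated calls over all calls in all 12 files (largest deviation 5e-07). Coordinates are those of the files. The gene table at hand is for assembly ASM3414082v1, and its last gene ends beyond the last window on all 12 chromosomes. It is therefore another build, and its coordinates were not used. For this reason the planned location of loci in genes, the levels over genes, the gene lists and the naming of genes by promoter were not analysed here. The part of the naming rule that needs no annotation was kept: the 5 loci with most called windows. Other loci named below were chosen after their values were seen, which is said where they appear.

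The ros1a/+ sperm CHH values stop within chromosome 6, at position 17438800, in the middle of a line, and hold nothing for chromosomes 7, 8 and 9. CHH levels of all 4 libraries and CHH values at loci were therefore limited to the part present in that library. CHH window comparisons that do not involve it used all chromosomes.

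Levels were computed from the calls summed over the 12 nuclear chromosomes, with Wilson 95% intervals. For each of 4 comparisons and 3 contexts, windows with at least 10 calls in both libraries were tested with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the windows of that comparison and context. A window was called when the adjusted p was under 0.05 and the level differed by at least 50 percentage points in CG or CHG, or 20 points in CHH. CG windows called lower in WT vegetative cell than in WT sperm were merged over gaps of up to 300 bp and kept with at least 100 bp of called windows. These are the vegetative-cell-low loci, and the opposite set was built in the same way. Overlaps of called windows were set beside the number expected of independent lists and, added after seeing the data, beside the number expected of unrelated lists within classes of starting methylation level (bins of 10 points in CG and 2 points in CHH) and 6 classes of depth, since windows must be methylated to be called lower. Levels at loci were pooled over windows with at least 10 calls in the libraries compared. Beside them stand windows outside the loci, matched in bins of 5 points on the mean of both sperm levels. Several calls in a window can come from 1 read or from PCR copies of 1 molecule. The p-values are then too small, and the intervals cover counting error only.

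On simulated data with the real depths and 200 changed windows per size, unchanged windows were called at most 1 time per comparison and context. The simulated calls were independent of each other. They give no rate of false calls where calls share reads or PCR copies. For CG in WT vegetative cell against WT sperm, 6.0% of falls of 40 points, 56.0% of falls of 60 points and 82.0% of falls of 80 points were recovered. For CHH in the same pair, falls of 30 points were recovered in 5.0% of windows and falls of 60 points in 52.5%. The changed windows were drawn from those at 80% or more in CG and at 60% or more in CHH. Only falls were simulated. The CHH values therefore give no recovery rate for rises from low levels, the direction of most CHH calls between the cell types.

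Total CG calls were 272624522 in WT sperm, 215899070 in WT vegetative cell, 182751393 in ros1a/+ sperm and 166471683 in ros1a/+ vegetative cell. The median window with a CG call held 19, 15, 13 and 13 calls in the same order. A level from 10 calls moves in steps of 10 points, so single windows are imprecise and the text leads with pooled levels.

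Thresholds, tests, comparisons and most alternatives were fixed before the data were examined. The alternatives changed the coverage minimum, the size of difference, the adjusted p, the weight of calls, the depth, the merging of windows, the libraries and windows that select the loci, the pooling and the chromosomes used. Alternatives chosen after seeing the data were loci called against each of the sperm libraries, loci called against the pooled sperm calls, loci called higher in ros1a/+ than WT vegetative cell, means of window levels per library, and a correction by the mitochondrial level. The pooled sperm alternative was added after the values of the one against each sperm library were known, because that one requires a high level in ros1a/+ sperm and so favours a difference near 0. The pooled calls lean to WT sperm, which had more calls. The analysis of methylated segments was also chosen after seeing the data. Segments were runs of windows at 50% or more CG in the pooled sperm calls, with at least 5 calls per window and windows below that bridged.

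Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Numba 0.67.0 and Matplotlib 3.10.9 were used.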

Results

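The data describe CG, CHG and CHH methylation in 50-bp windows of the rice nuclear genome in WT sperm, WT vegetative cell, ros1a/+ sperm and ros1a/+ vegetative cell, with 1 library each. The design sets the vegetative cell beside sperm in each genotype, and ros1a/+ beside WT in each cell type. The series addresses whether ROS1a removes DNA methylation in the vegetative cell and how methylation in sperm differs when it is reduced. All intervals cover counting error only.

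CG methylation was lower in the vegetative cell than in sperm in both genotypes. The CG level over the 12 chromosomes was 23.97% in WT sperm and 19.0% in WT vegetative cell, and 25.6% in ros1a/+ sperm and 23.4% in ros1a/+ vegetative cell. As the mean of window levels over the 2035506 windows covered in all libraries, the 4 values were 40.9%, 32.1%, 40.6% and 34.9%. CHH methylation was higher in the vegetative cell, at 4.89% against 2.31% in WT sperm and 5.62% against 2.88% in ros1a/+ sperm. CHG levels lay closer together, at 11.7% in WT sperm, 12.3% in WT vegetative cell, 12.2% in ros1a/+ sperm and 14.1% in ros1a/+ vegetative cell. As means of window levels over windows covered in all libraries, the CHG values were 14.5%, 15.6%, 13.7% and 15.7% in the same order. Between chromosomes, the CG level of WT sperm ran from 17.5% on chromosome 3 to 34.0% on chromosome 12, a wider range than the differences between libraries.

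In WT pollen, CG differences between the cell types went almost entirely one way. Of 2678723 windows tested, 200611 were called lower in WT vegetative cell than in WT sperm and 2630 were called higher, by Fisher's exact test with Benjamini-Hochberg adjustment. CHH went the other way, with 396464 of 5459554 windows called higher in WT vegetative cell and 12652 called lower. CHG windows were called in both directions, 23705 lower and 25591 higher. That small majority turned over under a stricter threshold, with 18914 lower and 16758 higher at an adjusted p under 0.01. The counts depended on the weight given to calls: with calls divided by the cytosines of a window, 48202 CG windows were lower and 390 higher, and 60 CHH windows were called, all of them higher.

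The called CG windows formed 41092 vegetative-cell-low loci that spanned 12.5 Mb, with a median length of 200 bp, against 200 loci of the opposite kind. The loci lay on every nuclear chromosome, from 97.0 per Mb on chromosome 3 to 124 per Mb on chromosome 11. The longest locus, chromosome 11 from 16499601 to 16505800, held 108 called windows. Its CG level was 97.2% in WT sperm (95% interval 96.7% to 97.6%) and 13.9% in WT vegetative cell (13.2% to 14.6%). CHG at this locus was 50.9% in WT sperm and 12.1% in WT vegetative cell, while CHH was 2.10% and 4.27%. The locus at chromosome 5 from 9052301 to 9055050 had CG levels of 96.9% and 30.3% in the same libraries, and the locus at chromosome 10 from 23124001 to 23126800 had 97.0% and 38.6%. The locus at chromosome 11 from 6187251 to 6189250 had 95.7% and 13.6%. At the longest locus the CG calls were 5465 in WT sperm and 8612 in WT vegetative cell. Over windows of all vegetative-cell-low loci with at least 10 calls in every library they were 6950720 and 7884102. WT vegetative cell had more calls there although its library held fewer CG calls in total. What caused this was not tested, so the sizes of these falls cannot be read as loss of methylation alone.

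**Figure D1:**
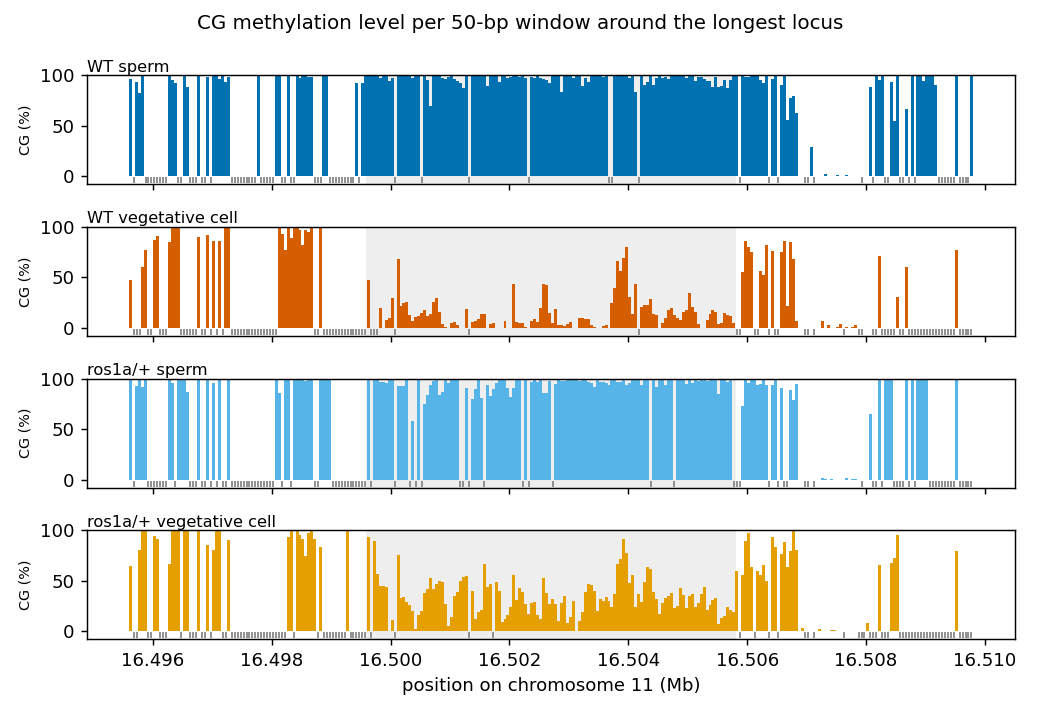
CG methylation level (percent, vertical axes) of each 50-bp window along chromosome 11 (position in Mb) in the 4 libraries, with the longest vegetative-cell-low locus shaded and grey ticks for windows with fewer than 10 calls. Inside the shaded region the pooled level was 97.2% in WT sperm, 13.9% in WT vegetative cell, 95.8% in ros1a/+ sperm and 33.1% in ros1a/+ vegetative cell.

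Vegetative-cell-low windows were most frequent in short stretches of methylated sequence, a relation examined after the data were seen. Of windows in methylated segments of up to 100 bp, 24.5% were called lower in WT vegetative cell than in WT sperm. The share was 31.0% in segments up to 200 bp, 30.8% up to 500 bp, 27.9% up to 1000 bp, 21.8% up to 2000 bp, 16.5% up to 5000 bp, 9.08% up to 20000 bp and 5.51% in longer ones. Over the 12 chromosomes the last share ran from 4.36% to 7.64%, and the share in segments up to 500 bp (above 200 bp) from 28.7% to 34.7%. In segments over 5000 bp, 26.5% of windows within 200 bp of an edge were called and 6.20% of windows 1000 bp or more inside. CHH was higher in WT vegetative cell in all of these classes, going from 3.77% in WT sperm to 12.9% in WT vegetative cell in the longest segments. CHG went there from 54.8% to 64.9%, and from 26.4% to 24.1% in segments above 500 and up to 1000 bp. The segments were selected on high sperm levels.

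**Figure D2:**
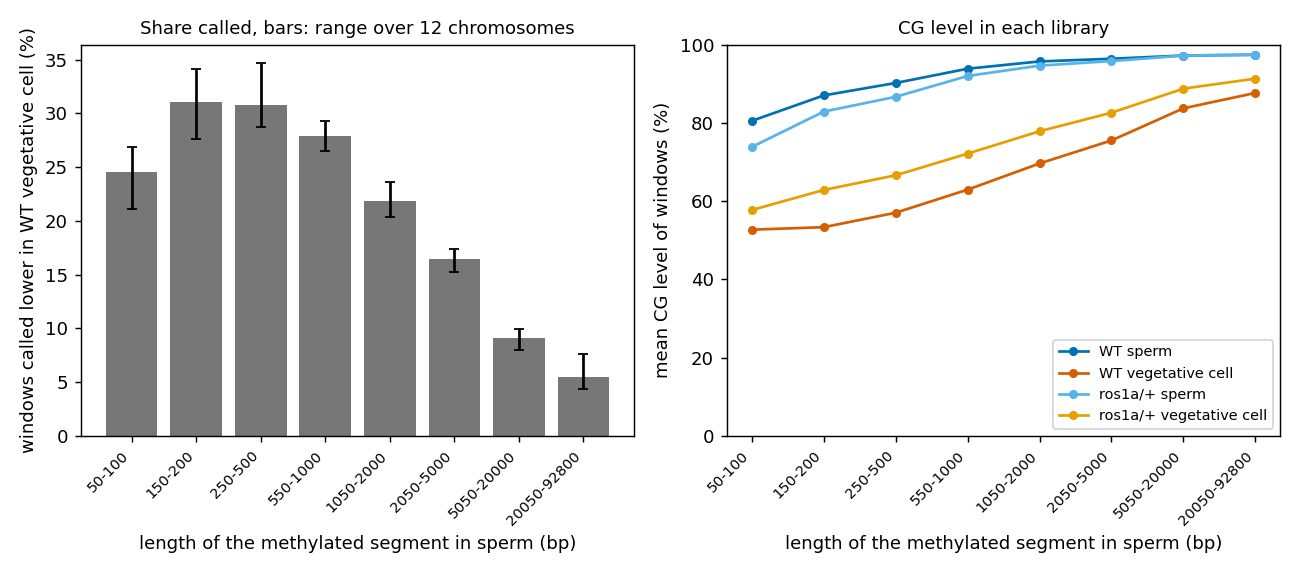
Left, the share of windows called lower in WT vegetative cell than in WT sperm (percent) by the length of the methylated segment in sperm (bp), with bars for the range over 12 chromosomes; right, the mean CG level (percent) of the same windows in the 4 libraries. The share fell from 31.0% in segments up to 200 bp (above 100 bp) to 5.51% in the longest segments, and the ros1a/+ vegetative cell lay between WT vegetative cell and sperm in each class.

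In ros1a/+ pollen, the CG difference between the cell types was smaller. Of 2257043 windows, 78537 were called lower in ros1a/+ vegetative cell than in ros1a/+ sperm and 4832 higher, and the mean window difference was -5.86 points against -9.57 points in WT. Of 139783 windows called lower in the WT pair and tested in both, 48975 (35.0%) were also called in the ros1a/+ pair, which made up 71.0% of the 68989 windows called there. The number expected was 4738 of independent lists, and 10558 of unrelated lists within classes of sperm CG level and depth, with no library in common. CHH was again higher in the vegetative cell, with 252867 of 3775167 windows higher and 11475 lower. The share called higher was 6.70%, against 7.26% in the WT pair, which was tested on all chromosomes. CHG was called higher in 27430 windows and lower in 8210. With calls divided by cytosines, 1333 CG windows were lower and 252 higher, 46 CHG windows were higher and 7 lower, and 36 CHH windows were called, all of them higher.

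**Figure D3:**
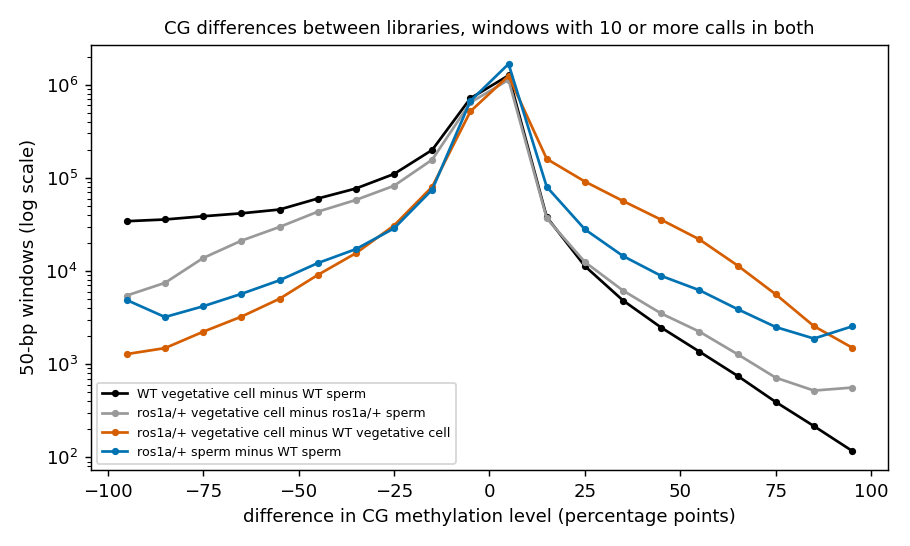
Number of 50-bp windows (log scale) by difference in CG methylation level (percentage points, bins of 10) for each of the 4 comparisons, over windows with at least 10 calls in both libraries. Differences between the vegetative cell and sperm extend to the negative side, where 34285 windows of the WT pair and 5456 of the ros1a/+ pair differed by more than 90 points. The ros1a/+ minus WT vegetative cell difference extends more to the positive side, with 1504 windows above 90 points and 1283 below -90. The sperm libraries also differed at both ends, with 4877 windows of ros1a/+ minus WT sperm below -90 points and 2543 above 90.

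The ros1a/+ vegetative cell had more CG methylation than the WT vegetative cell at the vegetative-cell-low loci. Over 143934 windows in these loci the CG level was 92.3% in WT sperm, 29.5% in WT vegetative cell, 87.2% in ros1a/+ sperm and 51.1% in ros1a/+ vegetative cell. The rise of 21.6 points (± 0.0503, 95% counting error) was 34.4% of the WT difference between the cell types and lay between 20.8 and 22.9 points on each of the 12 chromosomes. The difference in matched windows outside the loci was 2.59 points, from 79.7% in WT to 82.3% in ros1a/+ vegetative cell. These windows were matched on sperm levels only. They were already high in WT vegetative cell and had less room to rise, so their small difference is partly set by the selection. Of 37115 loci with at least 20 calls in every library, 93.2% were higher in ros1a/+ than in WT vegetative cell, with a median rise of 37.8% of the gap. The loci were selected as low in WT vegetative cell, and at loci called in the ros1a/+ pair the rise was 10.5 points. Across the genome 37861 CG windows were called higher and 12682 lower in ros1a/+ than in WT vegetative cell. With calls divided by the cytosines of a window the order turned over, with 761 higher and 960 lower.

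At the longest locus the ros1a/+ vegetative cell had 33.1% CG (32.0% to 34.2%) against 13.9% in WT. The loci on chromosome 5 and chromosome 10 had 50.5% and 57.9%, and the shorter locus on chromosome 11 had 46.5% against 13.6%. The locus on chromosome 6 from 12987751 to 12990150 was an exception among the 5, with 26.1% in ros1a/+ (24.5% to 27.6%) and 27.5% in WT vegetative cell (26.3% to 28.9%). CHG at the vegetative-cell-low loci was 5.69 points higher in ros1a/+ than in WT vegetative cell, and CHH was 1.24 points higher. At loci called in the ros1a/+ pair these differences were 1.58 points and 0.886 points. Genome-wide CHG calls between the vegetative cells were near balance, with 9219 higher and 10155 lower, and CHH calls were 76606 higher and 53509 lower. With calls divided by cytosines these were 32 and 72 in CHG, and no CHH window was called.

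**Figure D4:**
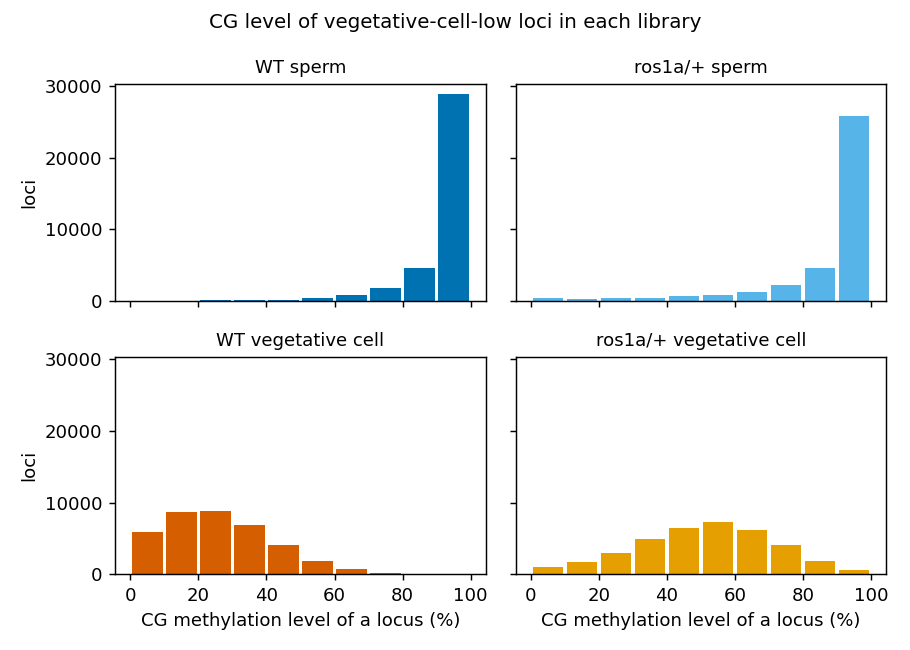
Histograms of the CG methylation level (percent, bins of 10 points) of vegetative-cell-low loci with at least 20 calls in every library, with the number of loci on the vertical axis and 1 panel per library. Of 37115 loci, 28891 were above 90% in WT sperm and 0 in WT vegetative cell, and the most frequent bin of ros1a/+ vegetative cell, 50% to 60%, held 7266 loci. The loci were built from windows at least 50 points lower in WT vegetative cell than in WT sperm, so the contrast of the WT panels is largely set by the selection.

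CG windows differed in both directions between the sperm libraries. Of 2650599 CG windows, 24945 were called lower and 15049 higher in ros1a/+ than in WT sperm. CHG windows were called lower more often, 9368 against 4052, and CHH windows higher more often, 22804 against 9921. The mean window difference was -0.334 points in CG, -0.902 points in CHG and 0.466 points in CHH. Weighted by calls, CG and CHG went the other way, with 25.6% CG in ros1a/+ sperm against 23.97% in WT sperm and 12.2% CHG against 11.7%. In the windows covered in all libraries these levels were 19.4% against 17.8%, and 9.15% against 8.74%. At windows with under 10% CG in both sperm libraries, CHH was also higher in ros1a/+ sperm, at 0.825% against 0.650%. Of the windows called higher in CG, 1702 were also called higher in ros1a/+ than WT vegetative cell, against 143 expected of independent lists and 194 within classes of starting level and depth. With calls divided by cytosines, 3386 CG windows were lower and 1353 higher, 13 CHG windows were lower and 2 higher, and no CHH window was called.

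At the vegetative-cell-low loci, the CG level of ros1a/+ sperm minus that of WT sperm was -5.05 points, against -0.857 points in matched windows. This difference depended on how the loci were selected, since WT sperm is one of the libraries that define them. At loci called in the ros1a/+ pair, ros1a/+ sperm was 4.46 points higher, and at loci called against the pooled calls of both sperm libraries, an alternative chosen after seeing the data, the difference was -0.707 points. Matched windows of that set differed by -1.03 points, so the remainder was 0.319 points and above 0 on 11 of 12 chromosomes, the opposite direction to the remainder of -4.19 points at the main loci. WT sperm supplied more of the pooled calls than ros1a/+ sperm, so that set also leans to windows high in WT sperm. At the 6190 loci called higher in ros1a/+ than WT vegetative cell, which use no sperm library, ros1a/+ sperm was 5.76 points higher and matched windows differed by -1.88 points. The remainder there was 7.64 points and above 0 on 12 of 12 chromosomes. Selection on the vegetative cells also takes in windows higher in ros1a/+ in both cell types. Across the genome these numbered 1702, or 8.75 times the number expected within classes of starting level and depth. This set of loci is therefore no neutral check of the sign in sperm. The locus on chromosome 6 named above had 96.5% CG in WT sperm and 36.7% in ros1a/+ sperm, from 1534 and 3149 calls.

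CHG at the vegetative-cell-low loci was 29.3% in ros1a/+ sperm and 33.9% in WT sperm, a difference of -4.54 points (± 0.0585). Matched windows differed by -2.56 points, so that -1.97 points remained, and the remainder was below 0 on 12 of 12 chromosomes. At the loci called against pooled sperm the remainder was -0.909 points, below 0 on 12 of 12 chromosomes. At the loci called higher in ros1a/+ than WT vegetative cell, the CHG difference was -1.07 points and that of matched windows -2.54 points, so the remainder was 1.48 points and above 0 on 11 of 12 chromosomes. CHH at the vegetative-cell-low loci was 3.997% in ros1a/+ sperm and 3.54% in WT sperm. Its rise of 0.457 points was below the 0.533 points of matched windows, with a remainder of -0.0770 points that was below 0 on 9 of 9 chromosomes with CHH values. Bins of 5 points are wide at such CHH levels, and the matched windows were at 2.98% in WT sperm. The CHH remainders, here and at the other sets of loci, therefore do not compare windows of equal level, and no conclusion is drawn from their signs. At the loci called against pooled sperm the CHH remainder was -0.0346 points, with 5 chromosomes below and 4 above 0, and at the loci called higher in ros1a/+ vegetative cell it was 0.0792 points. The CG, CHG and CHH remainders thus took both signs across sets of loci. In CHG and CHH the positive remainders came from the loci called higher in ros1a/+ than WT vegetative cell, which are no neutral check of sign.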

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

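The tests of explanations below were chosen after the result was seen, except the tests of relative depth and of CHH at windows with little CG methylation, which were set down before their values were computed.

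Sequences outside the 12 nuclear chromosomes, which no comparison used, carried methylated CG calls above the level that 3 calls would give. The chloroplast sequence had CG levels of 23.3% in WT sperm, 4.97% in WT vegetative cell, 19.7% in ros1a/+ sperm and 5.74% in ros1a/+ vegetative cell, from 528, 1770, 554 and 1603 calls. The mitochondrial sequence had 1.38%, 1.11%, 1.44% and 0.851% in the same order. The contig set named chrsy had 54.5%, 41.6%, 56.1% and 49.9%, and the contig set named chrun had 78.3%, 72.2%, 80.7% and 77.2%. The corresponding limits of 3 calls were at most 0.568%, for the chloroplast in WT sperm.

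CG windows lower in ros1a/+ than WT sperm numbered 24945, against 15049 higher. Loss at the windows whose methylation rises in the ros1a/+ vegetative cell would place them among those windows, but the overlap was 312 windows, against 264 expected of independent lists. That was 0.237 times the number expected of unrelated lists within classes of starting level and depth, and at most 0.413 times on any chromosome. Only windows called with a rise of at least 50 points count here, while the pooled rise at the vegetative-cell-low loci was 21.6 points. Windows with smaller rises lie outside the test, so it cannot exclude loss at those. A difference between the WT and ros1a/+ plants carried by both cell types is consistent with the overlap with windows lower in ros1a/+ than WT vegetative cell, 4096 windows against 94.6 expected of independent lists, or 16.5 times the number expected within classes, from 9.79 to 18.1 times by chromosome, with no library in common. It may account for the shared 22.1% of the windows that could be tested in both. The rest of the windows, and an effect of the ros1a genotype itself, stay open, since each genotype has 1 library per cell type.

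The CG rise in the ros1a/+ vegetative cell at vegetative-cell-low loci was 34.4% of the WT gap, and selection of windows low by chance in WT vegetative cell would leave no rise at loci called in the ros1a/+ pair, where it was 10.5 points and between 5.32 and 13.2 points on each chromosome. The uneven depth of the ros1a/+ vegetative cell library would make the rise differ along chromosomes, but the 127 bins of 1 Mb with the highest relative depth rose 1.01 times as much as the 127 with the lowest. Equal shares of WT nuclei and of mutant nuclei at the sperm level at every locus would give a median of about 50% of the gap. The median was 37.8%, from 36.0% to 38.9% by chromosome, and 39.6% at loci with at least 80% CG in ros1a/+ sperm. Equal shares with mutant nuclei below the sperm level at some loci would also lower the median and are not excluded. An incomplete loss of activity in mutant nuclei, unequal shares of nuclei and a difference between plants or single libraries may each apply. Windows higher in ros1a/+ in both cell types numbered 1702, or 8.75 times the number expected within classes, and 90 of them lay in the loci, which decides little because sperm levels there were too high for most windows to be called higher.

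The CHH level was higher in the vegetative cell than in sperm. Incomplete conversion would raise CHH everywhere, but at windows with under 10% CG in both sperm libraries the WT rise was 7.15e-05 times that at windows with 80% or more, and the ros1a/+ vegetative cell differed from ros1a/+ sperm by -0.224 points. The mitochondrial sequence did have more CHH in WT vegetative cell, at 0.879% against 0.667% in WT sperm. Corrected for these, the WT CHH levels were 4.04% in vegetative cell and 1.65% in sperm, so the rise remained. Chance differences at single windows would enrich calls of the WT and ros1a/+ pairs in opposite directions as much as calls higher in both, within classes of sperm level and depth. Calls higher in both were 2.50 times the number expected and opposite calls 0.222 times, a quotient of 11.3 that ran from 9.28 to 15.03 by chromosome. Differences between whole libraries unrelated to the cell type cannot be told apart from the cell type, since the ros1a/+ rise was 0.986 times the WT rise but 2 pairs rising together is an even chance. The cell type as labelled and other nuclei mixed into a library may each apply, untested.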

How the results depend on the processing

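Each group had 1 library, and no replicate numbers pair the libraries. A fit of cell type with genotype as a block, over the WT pair and the ros1a/+ pair, was not run. Its residual, 1 degree of freedom, would be the difference between the pairs, which the design also sets out to compare. The chloroplast correction was not run, since the few chloroplast calls give no background of unconverted cytosine, and the gene body region was not run for lack of an annotation of the build used. The levels against both sperm libraries, against pooled sperm, at loci higher in ros1a/+ than WT vegetative cell, as means of windows per library and with the mitochondrial correction were chosen after seeing the data. Except where a construction is named, the cause of a change was not tested. Counting intervals are so narrow that nearly every level moved beyond them.

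Order of libraries below is WT sperm, WT vegetative cell, ros1a/+ sperm and ros1a/+ vegetative cell. In windows with at least 10 calls in all libraries the CG levels were 17.8%, 15.04%, 19.4% and 18.9%, the CHG levels 8.74%, 9.63%, 9.15% and 11.2%, and the CHH levels 1.97%, 4.203%, 2.49% and 4.87%. As means of window levels they were 40.9%, 32.1%, 40.6% and 34.9% in CG, 14.5%, 15.6%, 13.7% and 15.7% in CHG, and 2.64%, 6.45%, 3.06% and 6.69% in CHH. Corrected for the mitochondrial level they were 22.9%, 18.1%, 24.5% and 22.7% in CG and 11.0%, 11.4%, 11.4% and 13.5% in CHG. In CHH the corrected levels were 1.65%, 4.04% and 4.98%, without ros1a/+ sperm, whose mitochondrial CHH was not analysed here. CG was lower and CHH higher in the vegetative cell than in sperm of the same genotype under each of these, except that ros1a/+ CHH has no corrected sperm value. The genotype order of CG and of CHG in sperm turned over with window means. The CHG levels of the vegetative cells then nearly met, at 15.6% in WT and 15.7% in ros1a/+.

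Order of comparisons below is WT vegetative cell against WT sperm, ros1a/+ vegetative cell against ros1a/+ sperm, ros1a/+ against WT vegetative cell, and ros1a/+ against WT sperm. With at least 20 calls, which leaves fewer windows to test, CG calls were 111982, 39888, 22919 and 18779, and CHG calls 21179, 13282, 8389 and 6145. The first CHG comparison then had 12309 lower and 8870 higher windows, the opposite majority. With the smaller difference of 30 points (10 in CHH) there were 145640, 104448 and 63066 CG calls in the last 3 comparisons, 107717, 74922, 43511 and 31661 CHG calls, and 50032 CHH calls between the sperm libraries. At an adjusted p under 0.01 the CHG calls were 35672, again with the opposite majority, 23246 in the ros1a/+ pair and 7897 between sperm, and the CHH calls 81306 between vegetative cells and 18370 between sperm. Thinned to equal depth, CHH calls between sperm were 18318.

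Dividing the calls of a window by its cytosines, which leaves the least evidence per window, had the largest effect on counts. CG calls were 48592, 1585, 1721 and 4739, CHG calls 530, 53, 104 and 15, and CHH calls 60, 36, 0 and 0. The majority turned over for CG between the vegetative cells, with 960 lower and 761 higher, and for CHG in the WT pair, with 407 lower and 123 higher. Under this setting the excess of CG windows higher in ros1a/+ than WT vegetative cell therefore did not hold. The number of vegetative-cell-low loci was 23739 with at least 20 calls, 10198 with calls divided by cytosines and 83591 with single windows kept. It was within 1.5 times the main count under the other alternatives, among them 28500 against both sperm libraries and 32589 against pooled sperm.

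The CG rise in ros1a/+ vegetative cell at the loci was 21.8 points with 5 calls, 21.9 with 20 calls, 23.6 as window means, 19.0 beyond matched windows, 22.0 in windows held out of the selection, 21.5 to 21.7 with 1 chromosome left out, 24.6 at loci low against both sperm libraries and 23.7 against pooled sperm. It was 10.5 points at loci called in the ros1a/+ pair, which are selected to be low in the ros1a/+ vegetative cell. The matched windows were at 79.7% in WT vegetative cell and had less room to rise than the loci.

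For sperm, in the same order of settings, the CG difference was -4.83, -5.50, -4.37, -4.19 and -4.62 points, with -5.14 to -4.73 on leaving out 1 chromosome. It was -0.0658 at loci low against both sperm libraries, which requires ros1a/+ sperm to be high, and -0.707 against pooled sperm, where WT sperm supplied more of the calls. It reversed to 4.46 at loci called in the ros1a/+ pair, selected on high ros1a/+ sperm, and to 5.76 at loci higher in ros1a/+ than WT vegetative cell. The latter selection also takes in windows higher in ros1a/+ in both cell types. The CHG difference was -4.18, -5.11, -4.75, -1.97 and -5.36 points, with -4.68 to -4.47 on leaving out 1 chromosome, and -3.83 under each of the settings with both sperm libraries. It was -3.09 at loci of the ros1a/+ pair and -1.07 at loci higher in ros1a/+ than WT vegetative cell. The CHH difference was 0.499, 0.409 and 0.438 points in the first 3 settings, reversed to -0.0770 beyond matched windows, and was 0.368 in held-out windows. It was 0.531 at loci of the ros1a/+ pair, 0.488 against both sperm libraries, 0.497 against pooled sperm and 0.473 at loci higher in ros1a/+ than WT vegetative cell. The windows matched for CHH had a lower WT sperm level than the loci, so the reversal beyond them does not compare windows of equal level.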

Other observations

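The following were chosen after the data were seen. The loci with most windows lower in ros1a/+ than WT sperm also differed between the vegetative cells. At chromosome 2 from 12979651 to 12983300, CG was 83.0% in WT sperm, 72.1% in WT vegetative cell, 1.09% in ros1a/+ sperm and 13.8% in ros1a/+ vegetative cell, and CHG was 36.6%, 33.6%, 0.484% and 3.67%. The CG calls there were 3628, 4892, 20218 and 11278, more in ros1a/+ although those libraries held fewer CG calls in total. At chromosome 4 from 12696801 to 12700100, CG was 95.6%, 88.8%, 29.3% and 33.0% in the same order, from 3817, 3496, 5450 and 6134 calls. At chromosome 2 from 11537351 to 11540300 it was 95.6%, 81.8%, 16.1% and 49.8%, from 2393, 1559, 1567 and 2104 calls. What caused the extra calls in ros1a/+ was not tested, and the falls cannot be read as loss of methylation alone.

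Among the 200 loci higher in WT vegetative cell than WT sperm, some were shared by the genotypes and some were not. At chromosome 4 from 20627651 to 20628250, CG was 6.14% in WT sperm and 81.6% in WT vegetative cell, and 11.1% and 86.2% in ros1a/+. The CG calls there were 2999 and 461 in WT, and 1325 and 181 in ros1a/+, a difference in depth whose cause was not tested. At chromosome 11 from 384401 to 384900, CG was 19.2% and 95.9% in WT, and 22.4% and 1.27% in ros1a/+, from 1055, 370, 1060 and 1259 calls. The 200 loci were selected as high in the WT vegetative cell library, which by itself lowers the other vegetative cell relative to it. Over their windows CG was 76.3% in WT vegetative cell and 30.4% in ros1a/+ vegetative cell, and 21.0% in WT sperm and 30.8% in ros1a/+ sperm. As a set they were thus not higher in the ros1a/+ vegetative cell than in ros1a/+ sperm, with a difference of -0.344 points.

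The depth of the ros1a/+ vegetative cell library relative to WT vegetative cell changed with methylation along chromosomes. In the 127 bins of 1 Mb with the lowest relative depth its median was 0.809 and the mean CG level of windows in WT sperm was 22.6%. In the 127 bins with the highest relative depth the median was 1.23 and the mean CG level was 60.97%.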
